A study of Mus musculus with 9 samples.

How the data were processed

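The data were 9 RNA-seq libraries of sorted YFP-positive mammary epithelial cells from female mice. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a low-input mRNA kit (SMARTer v4). The values deposited by the authors are FPKM, fragments scaled to transcript length and library size, in 1 table of 24043 rows. The header does not name the unit. FPKM was inferred from values that are not whole, sum to a different total in each library and step with gene length. Per the submitters' processing notes the genome build was mm9. The aligner, the quantifier and the annotation are not given in the sources used here. The reference annotation at hand was of another build, so no coordinates were used, and gene symbols are printed as in the table. Of the gene rows, 99.4% matched a current or older mouse symbol. The table held 92 spike-in rows, of which 1 was above 0, and these were left out. It also held 27 row names that read as dates.

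Some abundant genes were listed at exactly 0 in single libraries, which can be a failed estimate, so genes at 0 are given library by library. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Genes at 1 FPKM or more in at least 3 libraries were tested, 9503 in all. limma 3.58.1 in R 4.3.3 was fitted to the 9 libraries with 1 coefficient per genotype, leaving 6 residual degrees of freedom, with an intensity trend and robust moderation. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, called at 0.05. The 3 comparisons were p53-null against WT, p53/Brca1-null against WT and p53/Brca1-null against p53-null. The first and second share the WT libraries.

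For gene groups, 17 lists were fixed before the data were examined. They covered basal, luminal, hormone-sensing, luminal progenitor, milk, mesenchymal, p53 target, homologous recombination, cell cycle, interferon, NF-kB, immediate-early, immune, fibroblast, endothelial, adipocyte and red blood cell genes. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, 16 lists per comparison, with adjusted p over those lists. Camera compares a list with all other genes, while fry, an alternative named below, tests it against no change. The red blood cell list had 4 tested members and was not tested.

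The named genes followed a rule fixed before the data were examined. It took Trp53, Brca1, and per direction the 6 called genes with the largest change whose groups did not overlap and whose mean was at or above the median of all genes. Where fewer than 4 genes passed, the 6 with the smallest p were taken. Up to 3 called members per list were added, or else up to 2 members with the highest level. Genes outside the rule are said to be chosen after their values were seen, and members that passed adjusted over their list alone are named as such.

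The tests were checked on simulated data with 200 changed genes among 9503. For p53/Brca1-null against WT, 45.5% of genes changed 64-fold, 17.9% of those changed 16-fold and 6% of those changed 4-fold were called, with 0.032% of unchanged genes. For p53-null against WT these shares were 50%, 23.9% and 4.5%, and for p53/Brca1-null against p53-null 42.4%, 17.9% and 4.5%. Of the 67 genes changed 16-fold, 33 were raised, and low genes have little room to fall. In the top quartile of mean level, with 14 or 15 changed genes per fold, the shares were higher. They were 80%, 57.1% and 21.4% for p53/Brca1-null against WT and 80%, 71.4% and 14.3% for p53-null against WT. For p53/Brca1-null against p53-null they were 73.3%, 57.1% and 21.4%. All these shares describe the simulated data and may differ in the real libraries.

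Alternatives fixed before the data were examined were a replicate block, a fit of only the 6 libraries compared, limma without trend, quantile normalization, no filter, a filter of 5 FPKM, a pseudocount of 0.1, library weights, a log2 fold change threshold of 1, each library left out, and for lists an estimated correlation and fry. After the data were examined, 3 more were added. They were WT replicate 1 with an estimated share of WT replicate 2 subtracted, the number of detected genes as a covariate, and quantile normalization for lists.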

Results

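RNA was sequenced from mouse mammary epithelial cells that carried a yellow fluorescent protein (YFP) reporter and were sorted for it 1 month after an adenovirus was injected into the ducts. The virus expressed Cre recombinase under the promoter of keratin 8, a luminal keratin, so that Cre was aimed at luminal cells. The 9 libraries fell into 3 genotypes with 3 libraries each. One genotype had the reporter alone (WT), one also had floxed Trp53 (p53-null), and one had floxed Trp53 and floxed Brca1 (p53/Brca1-null). The values were FPKM, and their sums per library lay between 359976 and 433880. The read depth itself is unknown, but the steps between low values gave relative depths from 0.788 to 1.12, a range of 1.42 times. Each depth rested on the commonest ratio to p53-null replicate 3, held by 19 to 37 genes among 316 to 560 compared. The lowest depth was that of WT replicate 1, with WT replicates 2 and 3 at 1.09 and 1.01. The number of genes at 1 FPKM or more varied further: 4839, 7320 and 6105 in the WT libraries, 6286, 9146 and 9767 in the p53-null libraries, and 7332, 8213 and 7473 in the p53/Brca1-null libraries. The labels do not say whether the replicates of a genotype came from separate animals, so p-values measure the spread between these libraries, which may be technical.

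The 2 targeted genes were looked at first. Trp53, which encodes the p53 tumor suppressor, stood at 2.77, 25.5 and 1.35 FPKM in the WT libraries, at 55.7, 0.858 and 20.3 in the libraries labelled p53-null, and at 23.7, 26.5 and 1.88 in those labelled p53/Brca1-null. It was not lower in either null genotype: the log2 difference from WT was 1.09 ± 1.35 (SE) for p53-null (limma adjusted p = 0.784) and 1.02 ± 1.35 for p53/Brca1-null (limma adjusted p = 0.789). Between the null genotypes the log2 difference was -0.07 ± 1.35 (limma adjusted p = 0.999), and its sign turned with quantile normalization and with a smaller pseudocount. Brca1, a gene of homologous recombination, was listed at 0 in every library except p53-null replicate 1, at 0.00559 FPKM, and could not be tested. A recombined allele can still give reads outside its deleted exons, which values per gene do not separate. The values therefore do not check the genotypes, and groups are named by their labels throughout.

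The first comparison asked what differed with loss of p53 alone. Mrpl42, a mitochondrial ribosomal protein gene, was the 1 gene of 9503 that passed. It was listed at 0 in all 3 WT libraries and stood at 115.7, 61.0 and 93.4 FPKM in the libraries labelled p53-null (limma adjusted p = 0.00427). With fewer than 4 genes past the threshold, the others named are those with the next smallest p. Polr1c, a subunit of RNA polymerases I and III, stood at 0, 0 and 0.0337 FPKM in WT and at 51.8, 23.2 and 42.1 in p53-null (limma adjusted p = 0.110). Qdpr, which recycles tetrahydrobiopterin, stood at 0, 0.0289 and 0 against 39.6, 26.6 and 23.6 (limma adjusted p = 0.112). The galectin gene Lgals9 stood at 0.258, 5.49 and 0 against 56.8, 41.4 and 73.5, and 2210013O21Rik at 0.948, 0.0528 and 0 against 51.5, 22.1 and 32.1. The ribonuclease gene Ang3 went the other way, at 73.2, 10.7 and 16.9 FPKM in WT against 0.00118, 0 and 0.

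Luminal keratins did not pass. Krt8 stood at 1886 ± 481 FPKM (SD, n = 3) in WT and 2764 ± 1624 in p53-null, and Krt18 at 3259 ± 580 and 3671 ± 2277. None of the 14 luminal epithelial markers passed, nor did their list (camera adjusted p = 0.773), which passed as lower with the number of detected genes as a covariate (0.0133). The basal keratin Krt14 stood at 129.8 ± 34.7 and 345.5 ± 216 FPKM, and the list of 14 basal and myoepithelial markers did not pass (camera adjusted p = 0.482), but passed as higher without p53-null replicate 2 (0.000175) and with that covariate (0.0133). Among 27 tested p53 target genes none passed over all genes or adjusted over the list alone. Their median log2 change was 0.75, against 0.58 for all genes (camera adjusted p = 0.482). Cdkn1a, the cell cycle inhibitor p21, stood at 68.5 ± 41.5 FPKM in WT and 147.0 ± 77.4 in p53-null, and Bax at 79.2 ± 62.2 and 97.9 ± 51.3.

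Of 16 gene lists tested, 1 passed. The 18 immediate-early and handling stress genes, which are switched on within minutes of stimulation or tissue handling, fell relative to other genes, with a median log2 change of -0.14 against 0.58 for all genes (camera adjusted p = 0.0230). The call was lost at adjusted p = 0.910 with an estimated correlation. With quantile normalization the list lay -0.01 from other genes (0.777), and the number of detected genes as a covariate also ended the call (0.661). No member passed on its own over all genes or adjusted over the list alone. Atf3 stood at 696 ± 142 FPKM in WT and 575 ± 340 in p53-null, and Hspa1b at 421 ± 46.6 and 289 ± 142. Markers of other cell types varied with single libraries. Plvap, a marker of fenestrated endothelium, stood at 0.0262, 0.0758 and 40.5 FPKM in WT and at 286, 6.54 and 36.9 in p53-null. There replicate 1 also had the highest Fabp4, a gene of the adipocyte list, at 5145 FPKM. Of other genes in that list, chosen after their values were seen, Adipoq, Plin1 and Lep were listed at 0 in replicate 1. Pparg and Car3 stood at 19.2 and 137 FPKM. Adjusted over the list alone, 2 endothelial genes (Egfl7 and Esam), 1 adipocyte gene (Car3) and 1 immune gene (Coro1a) were higher, against 0 of each over all genes. Unlike Coro1a, 16 of the 20 immune markers lay below the median of all genes. Their list did not pass (camera adjusted p = 0.0881; adjusted p = 0.910 with an estimated correlation), but passed as lower without WT replicate 2 (8.6e-06) or p53-null replicate 3 (0.00267) and with the stricter filter (0.0360) or WT replicate 2 subtracted from WT replicate 1 (0.0365). The endothelial list did not pass either (camera adjusted p = 0.172; adjusted p = 0.910 with an estimated correlation), but passed as higher without WT replicate 3 (0.00891) or p53-null replicate 2 (0.00110) and with the covariate (0.00134).

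By limma, 1116 genes had an unadjusted p under 0.05 in this comparison, 1022 of them higher in p53-null. All genes leaned that way, with a median log2 change of 0.58. That median was 0.01 with the number of detected genes as a covariate and -0.04 with quantile normalization. Without p53-null replicate 1 or replicate 3 no gene passed, while 2, 5 and 8 genes passed without WT replicates 1, 2 and 3, and the immediate-early list was lost without WT replicate 1 (adjusted p = 0.102) or p53-null replicate 3 (0.391).

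The second comparison asked what differed with loss of both genes. In the libraries labelled p53/Brca1-null 24 genes passed, 21 higher and 3 lower than in WT. Retnla, a marker of alternatively activated macrophages chosen here after its values were seen, rose from 153.3 ± 75.3 FPKM (SD, n = 3) to 2525 ± 1136, a log2 change of 4.05 ± 0.47 (SE, limma adjusted p = 0.00160). The lectin genes Cd209g and Cd209f rose by 6.77 ± 0.90 and 6.65 ± 0.90 on the log2 scale. Cd209g stood at 0.0270, 0.0195 and 0 FPKM in WT and at 62.5, 236.7 and 88.5 in p53/Brca1-null, and Cd209f at 0.131, 2.98 and 0 against 82.5, 360.3 and 151.2. In p53-null neither was called, but both lay above all WT values. Cd209g stood there at 19.3, 13.5 and 31.7 FPKM and Cd209f at 20.2, 23.9 and 39.1. H2-Aa, an MHC class II chain, rose from 418 ± 86.8 to 1729 ± 323 FPKM, a log2 change of 2.05 ± 0.32 (limma adjusted p = 0.0105). Chosen after their values were seen, the chemokine genes Ccl6, Ccl24 and Pf4 and the coagulation factor gene F13a1 also rose, with log2 changes of 4.36, 4.68, 4.03 and 5.19.

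Other genes that rose were near 0 in WT. Mrpl42 was listed at 0 in all 3 WT libraries and stood at 102.2, 63.3 and 58.3 FPKM in p53/Brca1-null. Plb1, a phospholipase gene, rose by 5.58 ± 0.92 on the log2 scale, Cmtm3 by 5.37 ± 0.98 and the small GTPase gene Rab13 by 5.33 ± 0.93. Their p53-null means, not called, were 17.9, 11.6 and 13.8 FPKM. These lay between the means in WT (0.234, 0.653 and 0.0183) and in p53/Brca1-null (57.2, 61.9 and 46.4). Higher values than in WT were therefore not limited to p53/Brca1-null. Of 20 other settings, Mrpl42 passed in 20, Cd209g in 19, Cd209f in 18, H2-Aa and Plb1 in 14, Rab13 in 11 and Cmtm3 in 9. The 3 lower genes were Sprr1a, Ang3 and Gpx3. Sprr1a, a cornified envelope gene, stood at 110.6, 153.2 and 105.9 FPKM in WT and at 0, 5.05 and 0.535 in p53/Brca1-null (limma adjusted p = 0.00730). Gpx3, a secreted glutathione peroxidase, fell from 1581 ± 1157 to 242 ± 229.8 FPKM (limma adjusted p = 0.0446). Ang3 was listed at 0 in all 3 p53/Brca1-null libraries. Sprr1a passed in 19 of 20 other settings, Gpx3 in 9 of 20 and Ang3 in 5 of 17.

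**Figure D1:**
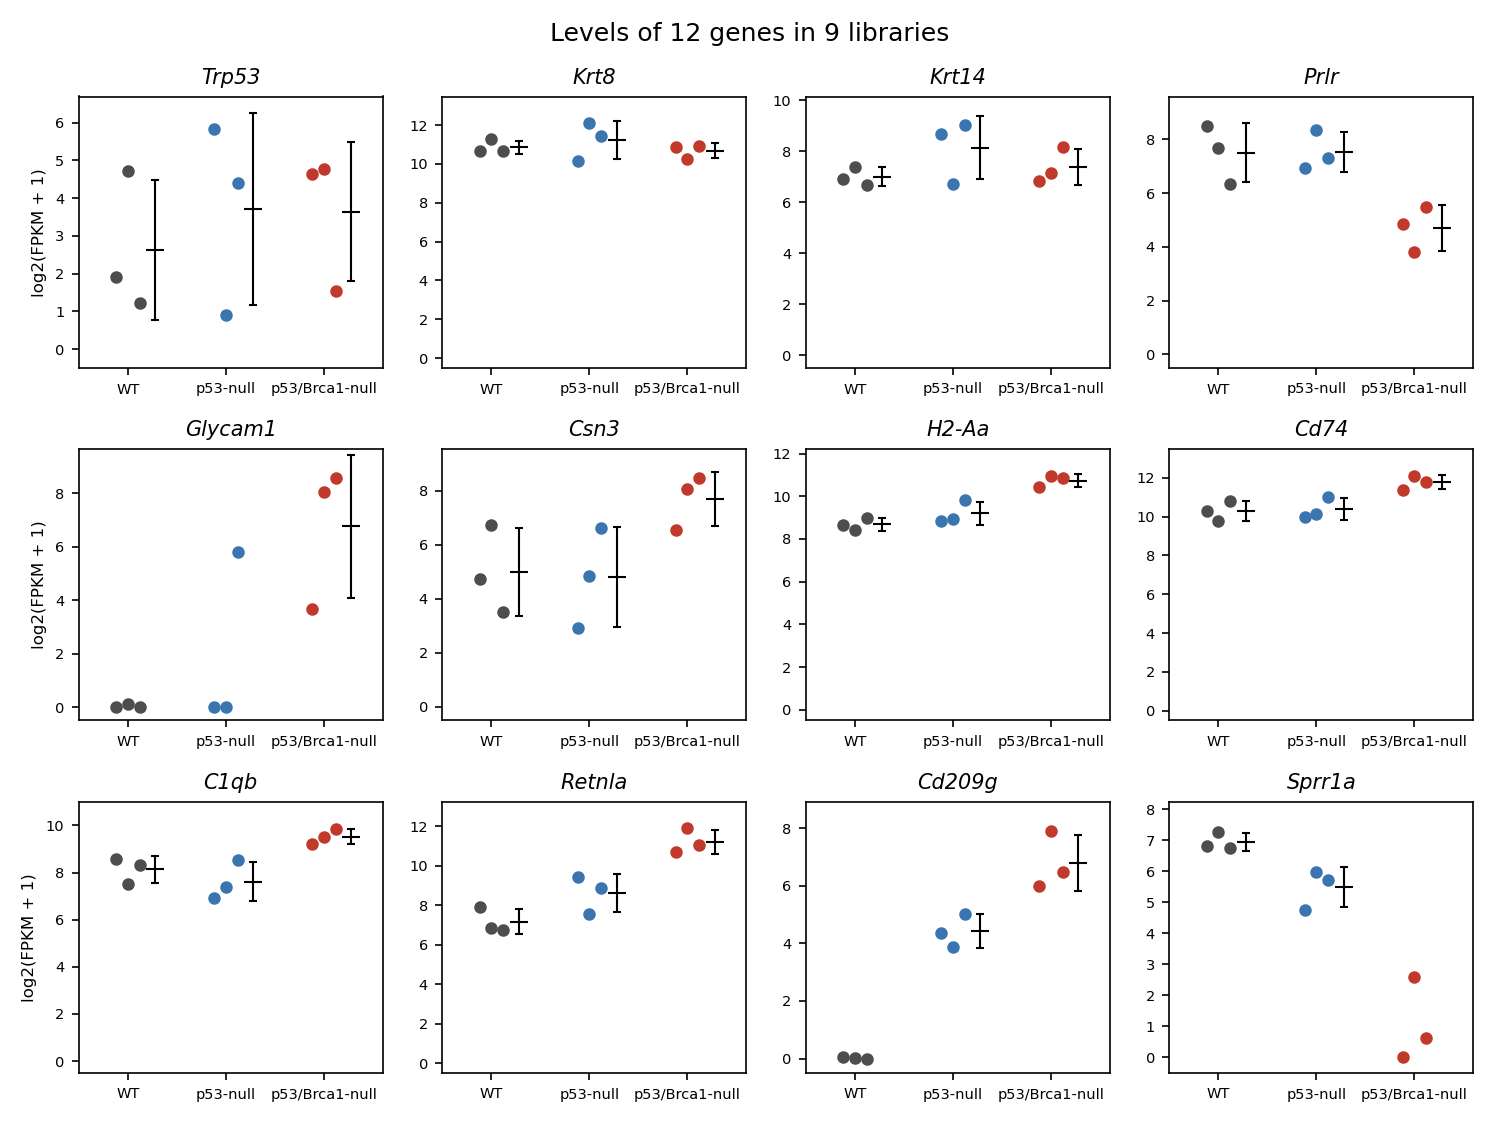
Levels of 12 genes as log2(FPKM + 1) in the 9 libraries, 1 point per library, with the mean ± SD of a genotype beside its points where none of its libraries was listed at 0. The 3 p53/Brca1-null points lie above all WT points for H2-Aa, Cd74, C1qb, Retnla, Cd209g and Glycam1. They lie below them for Prlr and Sprr1a, while Trp53 and Krt8 overlap between genotypes. Prlr, Glycam1, Csn3 and C1qb were chosen after their values were seen.

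By list, 5 of 16 passed in p53/Brca1-null against WT, and each was lost with an estimated correlation. The 20 immune cell markers rose relative to other genes, with a median log2 change of 1.28 against 0.41 for all genes (camera adjusted p = 0.000252; adjusted p = 0.604 with an estimated correlation). H2-Aa was the 1 member called over all genes, against 7 adjusted over the list alone, among them Cd74, C1qa and C1qb. The 17 milk and alveolar genes rose relative to other genes, with a median of 1.68 (camera adjusted p = 0.000796; adjusted p = 0.632 with an estimated correlation). No milk gene passed over all genes, and 5 passed adjusted over the list alone (Glycam1, Wap, Plin2, Trf and Csn3). The casein gene Csn2 stood at 89.9, 283 and 140.4 FPKM in WT and at 130.7, 2551 and 3753 in p53/Brca1-null, and Trf, transferrin, at 162 ± 169 and 660 ± 454. The 21 interferon-stimulated genes rose relative to other genes, with a median of 1.62 (camera adjusted p = 0.0327; adjusted p = 0.458 with an estimated correlation). Bst2 stood at 64.3 ± 34.1 and 112.7 ± 46.2 FPKM, and Zbp1 was the 1 member that passed adjusted over the list alone, against 0 over all genes. Isg15 stood at 135.4, 11.8 and 0.135 FPKM in WT and at 39.0, 49.7 and 53.9 in p53/Brca1-null. Its mean did not rise (49.1 and 47.5 FPKM), while its log2 change was 1.94 ± 1.23.

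The 11 hormone-sensing luminal markers fell relative to other genes, with a median log2 change of -1.10 (camera adjusted p = 0.000401; adjusted p = 0.458 with an estimated correlation). None passed over all genes, and 2 passed adjusted over the list alone: Prlr, the prolactin receptor, with a log2 change of -2.79 ± 0.65, and the growth factor gene Areg, with -1.56 ± 0.50. Areg stood at 211 ± 60.5 FPKM in WT and 73.2 ± 27.9 in p53/Brca1-null. The 18 immediate-early genes fell relative to other genes, with a median of -0.44 (camera adjusted p = 0.000796; adjusted p = 0.458 with an estimated correlation), and Atf3 and Fosb passed adjusted over the list alone against 0 over all genes. Luminal, basal, luminal progenitor, mesenchymal, cell cycle, homologous recombination, NF-kB, fibroblast, endothelial and adipocyte lists did not pass, with camera adjusted p from 0.196 to 0.943. In other settings the cell cycle list passed as higher without p53/Brca1-null replicate 3 (0.00236) and the fibroblast list without p53/Brca1-null replicate 1 (0.00886). With the number of detected genes as a covariate the luminal list passed as lower (0.00292) and the endothelial list as higher (0.0325). The p53 target list did not pass (camera adjusted p = 0.639), and Gdf15 was its 1 member adjusted over the list alone, at 0.702, 8.13 and 26.3 FPKM in WT and 105.3, 95.7 and 239 in p53/Brca1-null. Cd14 (luminal progenitor), Egfl7 (endothelial) and Car3 (adipocyte) were also higher adjusted over their lists alone, against 0 over all genes. The 4 tested red blood cell genes were too few for a list test, and 3 (Hba-a2, Hbb-bt and Hbb-b1) were higher adjusted over the list alone against 0 over all genes. Hbb-b1 stood at 18.4 ± 22.3 FPKM in WT and 153.8 ± 134.2 in p53/Brca1-null.

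By limma, 1163 genes had an unadjusted p under 0.05, and the count of 24 became 7 with only the 6 libraries compared, 6 with WT replicate 2 subtracted from WT replicate 1, 4 with the number of detected genes as a covariate, 73 without WT replicate 3, 8 and 12 without p53-null replicates 2 and 3, and 6, 3 and 7 without p53/Brca1-null replicates 1, 2 and 3. The immediate-early list was lost with the covariate (adjusted p = 0.104), the milk list without p53/Brca1-null replicate 3 (adjusted p = 0.180), the immune list without WT replicate 2 (0.299), and the interferon list without WT replicate 2 (0.399) or p53/Brca1-null replicate 2 (0.0888), with no filter (0.117) and with the stricter filter (0.0733).

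The third comparison asked what Brca1 loss added on a p53-null background. No gene passed by limma, with 450 genes at an unadjusted p under 0.05, of which 176 were higher and 274 lower in the libraries labelled p53/Brca1-null. The 6 genes with the smallest p are named for their values. Retnla stood at 448 ± 254.5 FPKM in p53-null and 2525 ± 1136 in p53/Brca1-null, a log2 difference of 2.60 ± 0.47 (limma adjusted p = 0.315). H2-Aa stood at 613 ± 244 and 1729 ± 323 FPKM. Crym, a thyroid hormone binding protein gene, stood at 32.7, 60.2 and 30.6 FPKM in p53-null and at 0, 0.0956 and 0 in p53/Brca1-null. Sprr1a stood at 25.9, 61.4 and 52.1 against 0, 5.05 and 0.535. Gemin2 was listed at 0 in all p53/Brca1-null and all WT libraries and stood at 20.1, 5.68 and 10.2 FPKM in p53-null. The tetraspanin gene Cd9 stood at 1303 ± 439 and 478 ± 124.6 FPKM.

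As lists, 5 of 16 passed, and none held with an estimated correlation. The 20 immune cell markers rose relative to other genes, with a median log2 difference of 1.48 against -0.16 for all genes (camera adjusted p = 4.3e-15; adjusted p = 0.290 with an estimated correlation). Adjusted over the list alone 7 were higher, against 0 over all genes: H2-Aa, H2-Ab1, Cd74, C1qa, C1qb, C1qc and Fcer1g. Cd74, the MHC class II invariant chain, stood at 1405 ± 592 FPKM in p53-null and 3550 ± 873 in p53/Brca1-null, and Lyz2, lysozyme, at 1011 ± 543 and 2599 ± 1009. The 17 milk and alveolar genes rose relative to other genes, with a median of 1.71 (camera adjusted p = 2.7e-10; adjusted p = 0.290 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Csn2 stood at 61.6, 2.24 and 725.6 FPKM in p53-null. The 21 interferon-stimulated genes were higher relative to other genes, with a median of 0.32 against -0.16 (camera adjusted p = 0.0209; adjusted p = 0.290 with an estimated correlation), while no member passed over all genes or adjusted over the list alone and Irf9, Stat2 and Cxcl10, chosen after their values were seen, stood lower. Bst2 stood at 77.0 ± 35.5 and 112.7 ± 46.2 FPKM, and Isg15 at 36.8 ± 19.0 and 47.5 ± 7.67.

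The 11 hormone-sensing luminal markers fell relative to other genes, with a median log2 difference of -1.20 (camera adjusted p = 0.000325; adjusted p = 0.290 with an estimated correlation). Prlr stood at 120.6, 322.9 and 155 FPKM in p53-null and at 27.8, 12.9 and 43.6 in p53/Brca1-null, and was the 1 member that passed adjusted over the list alone, against 0 over all genes. The 14 basal and myoepithelial markers fell relative to other genes, with a median of -0.90 (camera adjusted p = 0.0110; adjusted p = 0.602 with an estimated correlation). Krt14 stood at 345.5 ± 216 and 181 ± 95.9 FPKM, and Krt17 at 318.5 ± 178 and 159.8 ± 25.5. Of the markers of other cell types, the medians were -0.75 for 11 endothelial genes, -1.01 for 5 adipocyte genes and 0.09 for 10 fibroblast genes, none of which passed (camera adjusted p of 0.270, 0.423 and 0.423). Without p53-null replicate 1 the endothelial and adipocyte medians were -0.01 and -0.55, against -0.37 for all genes. The direction given by camera turned for both lists (camera adjusted p = 0.426 and 0.823), though the adipocyte median stayed below that of all genes. The endothelial list passed as lower without p53-null replicate 2 (0.000722) and with the covariate (0.0417), and the fibroblast list as higher without p53/Brca1-null replicate 1 (0.0220). The luminal list did not pass (camera adjusted p = 0.326), but passed as lower without p53-null replicate 1 (3.2e-05) and with quantile normalization (0.0390). The red blood cell gene Hbb-b1 stood at 27.9 ± 17.1 FPKM in p53-null and 153.8 ± 134.2 in p53/Brca1-null, a log2 difference of 2.02 ± 1.07 (limma adjusted p = 0.999). The p53 target list (camera adjusted p = 0.537) and the homologous recombination list (0.649) did not pass either.

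The basal list rested on p53-null replicate 1, and without it the adjusted p was 0.797, while leaving out p53-null replicate 3 or p53/Brca1-null replicate 2 and the stricter filter also ended that call (0.143, 0.134 and 0.0846). The interferon list was lost without p53-null replicate 2 (adjusted p = 0.318), p53-null replicate 3 (0.0529) or p53/Brca1-null replicate 2 (0.210), and with no filter (0.118), the stricter filter (0.0846) or the covariate (0.0582).

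**Figure D2:**
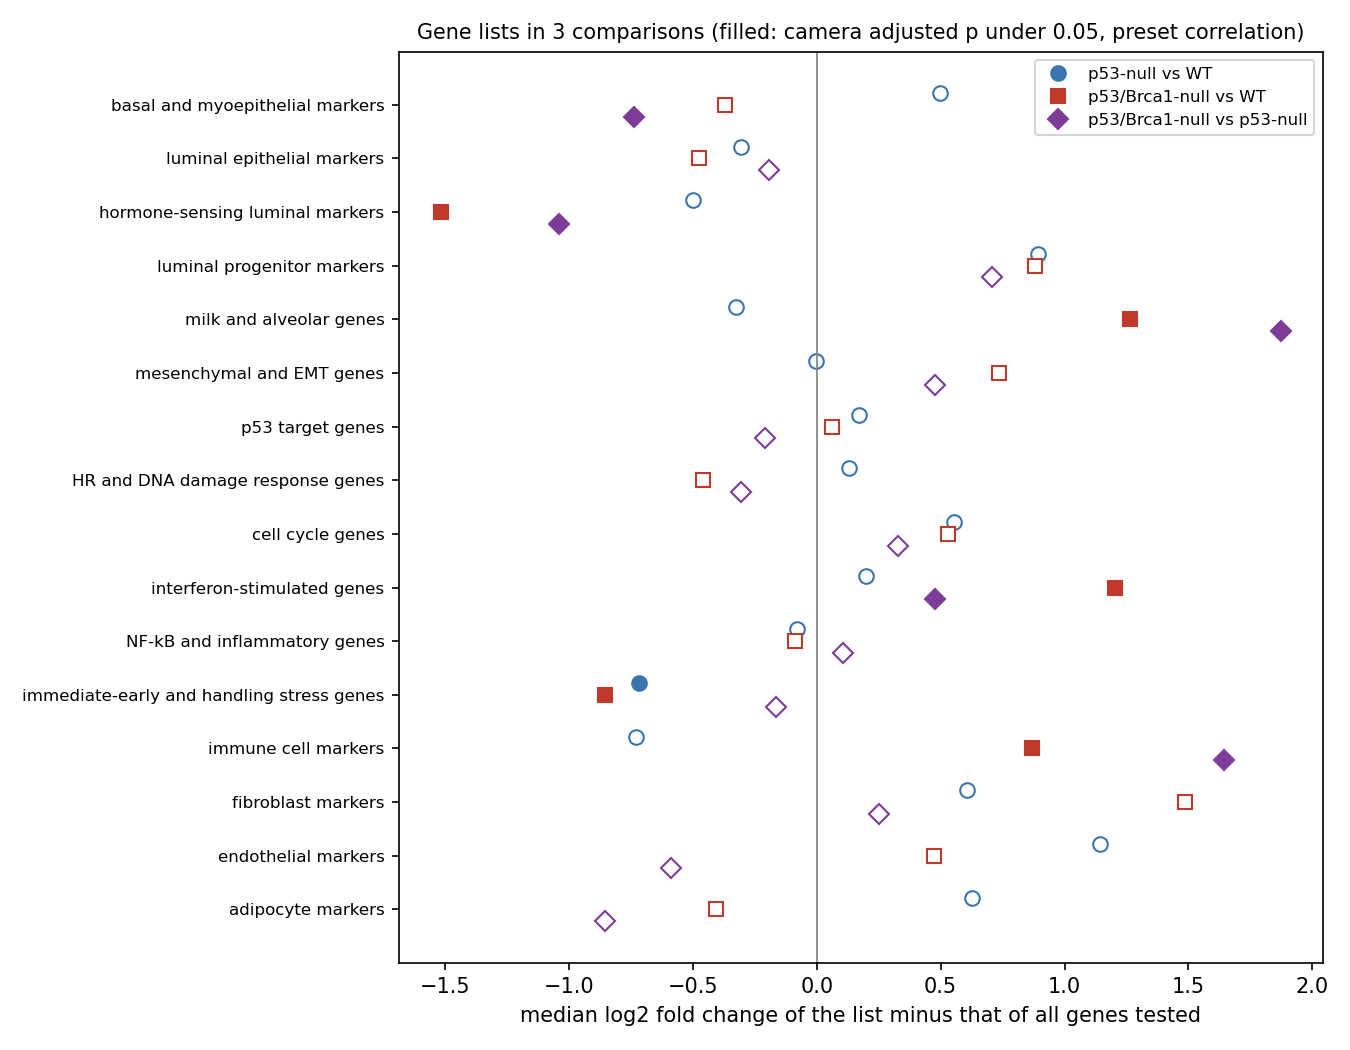
Median log2 fold change of each tested gene list minus the median of all 9503 genes, for the 3 comparisons, with filled symbols where camera with a preset correlation gave an adjusted p under 0.05. The immune and milk lists lie above 0 in both comparisons of p53/Brca1-null and the hormone-sensing list below 0, and with an estimated correlation no symbol would be filled.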

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

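Calls were few. Of the alternatives, 35 of 60 gene counts and 39 of 57 list counts stayed near the reported ones, that is, equal or within a fixed ratio. Among the gene counts are those between the null genotypes, which stayed at 0 in all 9 fits with a library left out. For p53/Brca1-null against WT 3 of 9 such fits stayed near. The fold change threshold could not change a count, since every called gene exceeded it. In number of genes, the count for p53/Brca1-null against WT moved most. The replicate numbers do not pair the libraries: correlations of same-numbered deviations ran from -0.083 to 0.056, and 0 libraries correlated best with their own number. With the replicate block 14 genes passed for p53/Brca1-null against WT in place of 24, 11 of them shared, and the other 5 counts of genes and lists stayed the same.

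For p53-null against WT the count of 1 gene became 0 with only the 6 libraries compared, 22 without the trend, 17 with a pseudocount of 0.1, 2 with library weights and 0 with the covariate, and ran from 0 to 8 with a library left out. For p53/Brca1-null against WT the count of 24 became 7 with only the 6 libraries, 50 without the trend, 45 with quantile normalization (36 higher and 9 lower), 56 with a pseudocount of 0.1, 16 with no filter (14 of them shared), 6 after subtraction of WT replicate 2 from WT replicate 1 and 4 with the covariate. It ran from 3 to 73 with a library left out. For p53/Brca1-null against p53-null, 1 gene passed with only the 6 libraries and 19 with library weights (3 higher and 16 lower). The cause was not tested, beyond the fewer genes and libraries some settings leave. Quantile normalization moved the median log2 change of all genes from 0.58 to -0.04 and from 0.41 to -0.04 against WT, and from -0.16 to 0.00 between the null genotypes.

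No list passed in any comparison with an estimated correlation or with fry, 0 in each. For p53-null against WT the count of 1 list became 0 with quantile normalization, 2 with the stricter filter, 2 after the subtraction and 3 with the covariate, and ran from 0 to 3 with a library left out. It ran from 3 to 6 in both p53/Brca1-null comparisons, and was 3 of 5 against p53-null with the stricter filter. Trp53 between the null genotypes turned from -0.07 to 0.17 with quantile normalization, 0.068 with a pseudocount of 0.1 and 0.30 with library weights, and ran from -1.47 to 0.99 with a library left out.

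Lists that passed in neither setting changed direction as follows, by adjusted p. The direction by fry is against no change and not against other genes, so there a difference is not a reversal of the same quantity. For p53-null against WT, these were luminal 0.777 (quantile) and 0.749 (fry), hormone-sensing 0.749 (fry), milk 0.946 (fry), mesenchymal 0.969 (6 libraries), 0.862 (quantile), 0.626 (stricter filter) and 0.297 (fry), NF-kB 0.969 (6 libraries), 0.813 (quantile), 0.448 (fry) and 0.661 (covariate), homologous recombination 0.862 (quantile) and 0.887 (no filter), and fibroblast 0.887 (no filter). For p53/Brca1-null against WT, these were basal 0.951 (fry) and 0.669 (covariate), luminal 0.951 (fry), homologous recombination 0.833 (pseudocount), 0.383 (fry) and 0.744 (covariate), and adipocyte 0.937 (replicate block), 0.961 (stricter filter) and 0.833 (pseudocount). Adipocyte was 0.797 with no filter against p53-null.

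With a library left out, direction also changed for these lists, with adjusted p ranges over all 9. For p53-null against WT, basal ran from 0.000175 to 0.838, luminal from 0.0934 to 0.810, milk from 0.0135 to 0.911, mesenchymal from 0.602 to 0.987, homologous recombination from 0.576 to 0.977, interferon from 0.296 to 0.934, NF-kB from 0.666 to 0.937 and adipocyte from 0.296 to 0.934. For p53/Brca1-null against WT, homologous recombination ran from 0.607 to 0.927, NF-kB from 0.226 to 0.969, endothelial from 0.0521 to 0.922 and adipocyte from 0.727 to 0.980. For p53/Brca1-null against p53-null, luminal ran from 3.2e-05 to 0.971, homologous recombination from 0.238 to 0.809, cell cycle from 0.00323 to 0.971, immediate-early from 0.0185 to 0.797, fibroblast from 0.0220 to 0.764, endothelial from 0.000722 to 0.459 and adipocyte from 0.298 to 0.823. Beside the calls given with each comparison, further calls were gained that way. Milk genes were lower in p53-null than in WT without p53-null replicate 3 (0.0135). Between the null genotypes, immediate-early genes were lower without p53-null replicate 3 (0.0185), and cell cycle genes higher without p53/Brca1-null replicate 3 (0.00323). The cause was not tested. Over all list settings, fry included, 787 of 905 kept direction and side, 43 lost a call, 22 gained one and 53 changed direction. For genes named as called or for their smallest p, 352 of 431 kept both, 63 lost a call, 16 gained one and 0 changed sign. For members named for their level or list, 93 of 1999 alternatives changed sign and 57 moved beyond the spread. With a library left out, p53-null against WT ran from -0.50 to 0.52 for Krt18, from -0.91 to 0.44 for Cited1, from -3.44 to 0.47 for Csn2 and from -0.35 to 1.38 for Trf.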

Other observations

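Chosen after the results were seen were both tests of WT replicate 1, the comparisons of immune genes with other cell types, the subtraction and covariate alternatives and the counts of splits. The macrophage and lymphocyte tests and the test of undetected genes were written before their results were seen.

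A list of 30 further macrophage genes, none of them in the immune list, had 26 tested members. Between the null genotypes their median log2 change lay 1.69 above that of all genes, with 23 of 26 above it (camera p = 6.6e-12; p = 0.0169 with an estimated correlation), and 0 passed singly by limma. Against WT it lay 1.62 above in p53/Brca1-null (camera p = 6.9e-05; p = 0.106 with an estimated correlation) and -0.36 in p53-null (camera p = 0.129). The camera p-values of the macrophage and lymphocyte lists were not adjusted for the number of tests. Chosen after their values were seen, Cbr2, Cd68 and Mpeg1 show the range. Cbr2 stood at 2.38, 24.0 and 34.7 FPKM in WT, 157, 30.7 and 77.0 in p53-null and 168, 400.5 and 116.5 in p53/Brca1-null. Cd68 stood at 152.4, 52.8 and 103.3 in WT, 31.9, 44.1 and 61.8 in p53-null and 107.8, 180.4 and 166.3 in p53/Brca1-null. Mpeg1 went the other way, at 11.9, 10.9 and 14.8 in p53-null and 0.504, 5.07 and 8.36 in p53/Brca1-null.

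The higher immune markers of p53/Brca1-null against p53-null were weighed against cell makeup. A lower share of epithelial cells, with the other cell types in fixed proportion, would raise each of those alike. A lower share through a rise of 1 cell type alone would not. The contrasts between cell types therefore bear only on the first form. The immune median exceeded the endothelial median by 2.23 (permutation p = 0.00129 over genes, which are correlated), and by 1.27 without p53-null replicate 1 (permutation p = 0.0196). The adipocyte contrast was 2.50 (permutation p = 0.00670) and 1.81 without that library (permutation p = 0.0578). It rested on 5 genes, without Adipoq, Plin1 or Lep. The fibroblast contrast was 1.39 (permutation p = 0.0113) and 1.18 without that library (permutation p = 0.0327). Between libraries the immune minus endothelial scores overlapped, at -0.06, 4.28 and 2.96 in p53-null and 4.58, 3.45 and 4.97 in p53/Brca1-null (exact permutation p = 0.2), and so did those against fibroblast genes (exact permutation p = 0.4). Those against adipocyte genes did not overlap (exact permutation p = 0.1, the lowest that 20 arrangements allow). The immune minus red blood cell scores, over 4 red blood cell genes, varied widely. They were -0.73, 2.56 and 0.46 in p53-null and -0.51, -0.97 and 3.1 in p53/Brca1-null. Their mean difference of -0.22 lay within that spread (exact permutation p = 0.9). The luminal list, which a lower epithelial share would bring down, did not pass (camera adjusted p = 0.326) but passed as lower without p53-null replicate 1 (3.2e-05). These go both ways, so a lower epithelial share stays open. More macrophages among the sorted cells is a candidate explanation that predicts the rise of the further list, 1.69 above all genes. It would itself lower the epithelial share. The further list was written after the higher immune markers were seen. It holds genes of cells that the immune list also marks, so its rise is not separate support. The sort for YFP should remove cells that never met Cre, but transcripts of macrophage genes were present in WT too. Chosen after their values were seen, Lyz2 stood at 2119, 592 and 3223 FPKM in WT and C1qb at 385, 180 and 315. Emr1 stood at 0, 0.0564 and 0 there. T and B lymphocyte genes lay 0.18 above all genes (camera p = 0.456; p = 0.760 with an estimated correlation), which leaves more lymphocytes open. Expression of these genes by epithelial cells with the p53/Brca1-null genotype was not tested and stays open.

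Low values of WT replicate 1 followed WT replicate 2. Of 1064 genes at 50 FPKM or more in WT replicate 2, 21.8% stood in replicate 1 within 1 narrow ratio window around 8.29%, against at most 8.86% in the other 71 ordered pairs of libraries, and reads or RNA of replicate 2 in replicate 1 may account for it. Among these genes 0 stood above 0 but under a fixed ratio of 4% in replicate 1, against 64 to 134 for the other libraries as source. Over all other ordered pairs that count ran from 0 to 134, so a count of 0 is not particular to this pair. A further 7 genes were listed at exactly 0 in replicate 1, which a carried share of 8.29% would not give unless those estimates failed. In the reverse direction the share was 7.15%. That window reached up to a ratio of 20%; a bound of 12.6%, tried after the values were seen, gave 3.62% in reverse and left 21.8% as it was. RNA of 1 mouse in both libraries would put genes at ratios near 1, so the 21.8% at 1 low ratio in 1 direction argues against it as the source of this pile. Whether the libraries share a mouse stays open. Their Spearman correlation of 0.899 was above the 0.875 of the next pair, but reads of replicate 2 in replicate 1 would raise it too. No biological explanation was tested.

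Most genes called against WT were near 0 in WT. WT replicates 1 and 3 detected the fewest genes at 1 FPKM or more, 4839 and 6105, but WT replicate 2 with 7320 exceeded p53-null replicate 1 with 6286. Below 1 FPKM in all 3 WT libraries and at 10 or more in the other 6 were 11 of 1837 genes, 20.6 times the 0.53 expected if libraries missed genes independently. Of the other 83 trios of libraries 10 reached that ratio, up to 5512.5 where almost none were expected, with at most 5 such genes in another trio (a count looked at afterwards). The ratio is unstable, and since low values of WT replicate 1 follow WT replicate 2 these libraries were not independent, so the explanation stays open. Loss of p53 and Brca1 stays open beside it.

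With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, the real counts of 1, 24 and 0 stood beside highest other counts of 1, 0 and 3, and 3, 1 and 10 splits gave as many. For lists, the real counts of 1, 5 and 5 stood beside highest other counts of 5, 5 and 7, and 10, 3 and 5 splits gave as many, so the preset correlation called lists in mixed groups too.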
